A study of Medicago truncatula with 24 samples.

How the data were processed

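Total RNA was extracted from seedling roots of Medicago truncatula A17 and sickle, mock treated or grown in vermiculite inoculated with homogenised mycelium of Rhizoctonia solani AG8, and stranded libraries were sequenced, per the labels' protocols. The 24 libraries form 8 groups (line, treatment and day), with 3 replicates in each that the labels call biological. Libraries were prepared and sequenced by either of 2 providers per the labels' protocols, and which provider handled which library is not given in the sources used here, so a provider effect could not be examined.

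The submitters' processing notes name, without roles, bcl2fastq 2.17.1.14, cutadapt, TopHat2, SAMtools 0.1.19, HTSeq, edgeR and R 3.2.2. The genome build, the annotation release and the filter on low counts are not given in the sources used here. The only file analysed was a table of the authors' own results. Per the file headers, the authors deposited a fold change on a log scale and an FDR for each feature in A17 and in sickle at 2 and at 7 days after inoculation, 8 value columns in all. The fold changes were read as log2 because edgeR, which the submitters' processing notes name, writes base 2, and the deposited FDR was read as a p-value adjusted over the features of its comparison. The headers name line and day but not the direction, which was read as inoculated over mock. The authors' table gives no value for 2329 features in A17 and 2025 in sickle at 2 dpi, and for 1350 and 1496 at 7 dpi. The reason is not given in the sources used here, and such features were left out of the comparisons concerned.

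The depth of each library is unknown, and the table has no counts, standard errors or values per library. No interval of a fold change could be given and the spread between replicates could not be recomputed: it enters only through the authors' FDR. Tests planned before the data were examined were fits to values per library. They were replaced by counts of features with a deposited FDR below 0.05, a limit set here, and by overlaps and tests across features. Differences between the lines in mock or in inoculated roots, and formal interactions of line with treatment or day, were not analysed here.

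The table lists 19778 features at 19536 loci. At 239 loci there is more than 1 feature (481 features), and each feature was counted on its own. The 23 gene lists fixed before the data were examined were defined by gene names or descriptions, and 0 of the 19778 IDs matched the reference table of assembly MtrunA17r5.0-ANR, so no list was tested. The planned rule for named genes was reduced for the same reason to 4 features: the largest rise and the largest fall over both lines among the changed features at 2 dpi and again at 7 dpi. That reduction was chosen after the values were seen. Chromosome and order along it were read from the ID, and 411 features whose IDs name none of the 8 chromosomes were left out where position was used.

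Overlaps were tested by one-sided Fisher's exact tests over features with a value in both comparisons, with the size expected of independent lists given beside them. Medians of feature sets were compared by permuting features between sets, and paired differences between lines by flipping their signs with the mean difference as the statistic, two-sided, with 100000 resamples, or exactly for paired sets of up to 16 features. Adjacent changed loci were counted along the listed loci of each chromosome and set against 100000 random placements (one-sided). Values were adjusted by the Benjamini-Hochberg method within each family of tests. Rank correlations under the alternatives were set against an approximate 95% interval of the reported value by Fisher's z transformation over features, which is too narrow where features move together. All tests across features treat features as units, and features are not independent replicates.

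The FDR was turned back into a p-value by inverting the Benjamini-Hochberg adjustment, and the p-value and the log2 fold change into an approximate standard error under a normal distribution. This was done for features with an FDR below 0.5 in both of the comparisons set side by side, because FDRs near 1 carry little of the p-value, and was checked on simulated data. A test of single features for a difference between lines or days was built on these errors and is not reported, because that limit leaves out the features that respond in 1 comparison alone and so fixes much of its outcome.

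Alternatives were an FDR limit of 0.01 and an added change of at least 2-fold, planned before the data were examined, and, chosen afterwards, an FDR limit of 0.1, 1 feature per locus, and only the 16351 features with a value in all 4 comparisons. Computation used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.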

Results

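Root RNA from Medicago truncatula, a model legume, was sequenced after inoculation with the soil-borne root-rot fungus Rhizoctonia solani AG8. A17, the wild-type line, is moderately resistant to this fungus per the labels, and sickle, a mutant of A17 that does not respond to ethylene, is highly susceptible. Each line was mock treated with water or inoculated and harvested at 2 or 7 days after inoculation (dpi), which gave 8 groups of 3 biological replicates, or 24 libraries. The values analysed were those of the authors' deposited table, which holds a log2 fold change and a false discovery rate (FDR) for each transcript feature in 4 comparisons of inoculated with mock roots, 1 per line and day. The depth of each library is unknown, and the table carries neither a spread nor an interval for any fold change. A feature is described as induced or repressed when its FDR was below 0.05. Each line and day had its own mock group in the labels, so the 4 comparisons shared no libraries.

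Most of the features that changed were induced, in both lines on both days, with fold changes read as inoculated over mock. Induced features made up 81.9% of the 166 features that changed in A17 at 2 dpi and 92.1% of the 466 that changed in A17 at 7 dpi. In sickle they made up 72.3% of the 101 that changed at 2 dpi and 85.0% of the 147 that changed at 7 dpi. In total 700 of 19778 features changed in at least 1 comparison, and 2 changed in all 4. The files do not pair the feature IDs with gene names, so the response is described by the sizes of the responding sets, their fold changes and their positions, and 4 features are given by ID.

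**Figure D1:**
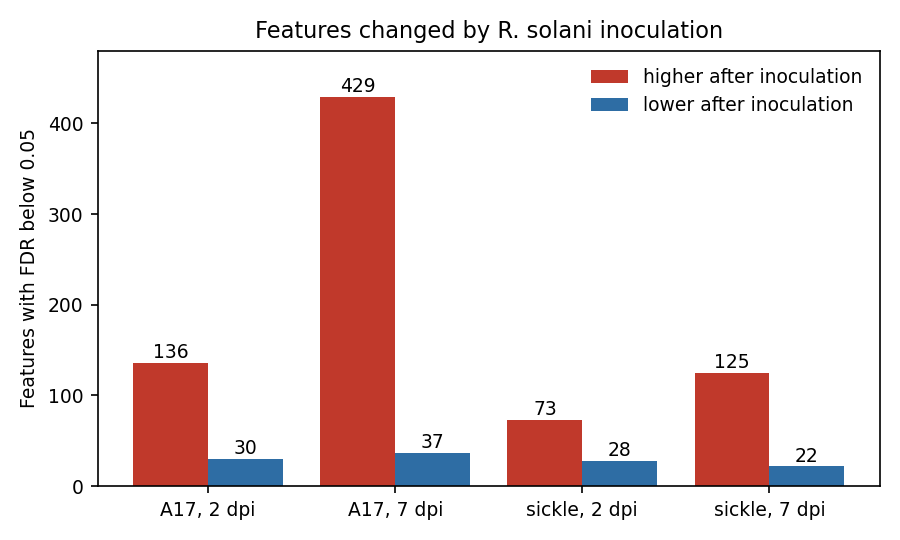
Number of transcript features with an FDR below 0.05 in the authors' deposited table, for A17 and sickle roots at 2 and 7 dpi. Red bars count features higher after inoculation and blue bars features lower after inoculation, and A17 at 7 dpi has the tallest bar with 429 induced features.

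The first comparison asked how roots of the wild type respond early in the infection. At 2 dpi, 136 features were induced and 30 repressed in A17, out of 17449 with a value. The induced features rose by a median log2 of 2.31, or 4.96-fold, and the repressed ones had a median log2 fold change of -2.02. In the authors' deposited table the induced features ranged from 1.41 to 10.43 on the log2 scale and the repressed ones from -3.32 to -1.32. The feature with the largest rise in either line at this time was Medtr3g008140.1, on chromosome 3 by its ID, with a log2 fold change of 10.43 (FDR 1.08e-12) in A17 and 7.89 (FDR 1.6e-14) in sickle in the authors' deposited table.

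More features had changed in the wild type by 7 dpi. In A17, 429 features were induced and 37 repressed out of 18428 with a value. The induced features rose by a median log2 of 2.90, or 7.45-fold, and the median of the repressed ones was -2.81. The authors' deposited table listed 61 features at a log2 of 5 or more in A17 at 7 dpi, of which 60 were induced, against 7 of 7 at 2 dpi. The largest rise was that of Medtr5g073200.1, on chromosome 5 by its ID, with a log2 fold change of 13.53 (FDR 1.19e-12) at 7 dpi and 7.27 (FDR 0.0302) at 2 dpi in A17 in the authors' deposited table, which has no value for it in sickle. Medtr3g008140.1 was at 12.35 (FDR 9.68e-84) in A17 at 7 dpi in the authors' deposited table.

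The early and late wild-type responses shared many features. Of the features with a value on both days, 130 were induced at 2 dpi and 354 at 7 dpi, and 64 were induced on both, where 2.71 would be shared by independent lists (one-sided Fisher's exact test, p = 2.13e-73, adjusted 1.28e-72 over 12 overlaps). The features induced at 2 dpi had a median log2 fold change of 2.15 at 7 dpi, and 100 of 130 were above 0. The features induced at 7 dpi had a median of 0.85 at 2 dpi, and 306 of 354 were above 0 then. Of the repressed features, 2 with a value on both days were repressed on both (0.0402 by independent lists, one-sided Fisher's exact p = 0.000729, adjusted 0.000972), and 2 features repressed at 2 dpi were induced at 7 dpi.

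The sickle comparisons asked how roots that do not respond to ethylene respond to the fungus. At 2 dpi, 73 features were induced and 28 repressed in sickle out of 17753 with a value. The median rise was 2.30 on the log2 scale, or 4.92-fold, and the median of the repressed features was -2.09. The median rise was close to the 2.31 of A17 on that day. Each median covers only the features that passed the FDR in its own line, so their closeness does not compare the sizes of the response. The largest fall in either line at 2 dpi was that of Medtr7g103390.1, on chromosome 7 by its ID, with a log2 fold change of -3.56 (FDR 0.0186) in sickle and 0.89 (FDR 1) in A17 in the authors' deposited table. At an FDR below 0.01, 66 features changed in sickle at 2 dpi.

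At 7 dpi, 125 features were induced and 22 repressed in sickle out of 18282 with a value. The induced features rose by a median log2 of 3.99, or 15.9-fold, and the repressed ones had a median of -4.25. In this comparison 21 of 487 features with a log2 rise of 2 to 3 passed the FDR, and 5 of 138 with such a fall. These medians therefore lean on large fold changes and cannot be set against those of A17 as sizes of the response. The largest fall of the whole table was that of Medtr6g015830.1, on chromosome 6 by its ID, with a log2 fold change of -8.19 (FDR 6.49e-08) in sickle at 7 dpi in the authors' deposited table, which gives no value for it in the other comparisons. Medtr3g008140.1 had a log2 fold change of 5.02 in sickle at 7 dpi in the authors' deposited table, with an FDR of 0.266 that did not pass. The number of changed features depended on the limit more than in the other comparisons, with 61 at an FDR below 0.01 and 228 at an FDR below 0.1.

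A fold change of a given size passed the FDR less often in sickle at 7 dpi than elsewhere. Of the features with a log2 fold change of at least 2 and below 3, 21 of 487 (4.31%) passed in sickle at 7 dpi, against 173 of 271 (63.8%) in A17 at 7 dpi, 59 of 81 (72.8%) in A17 at 2 dpi and 27 of 41 (65.9%) in sickle at 2 dpi. The shares of the 2 lines at 7 dpi differed (two-sided Fisher's exact test over features, which are not independent replicates, p = 3.24e-74). In all, 804 features were at a log2 of 2 or more in sickle at 7 dpi and 485 in A17, of which 124 and 378 were induced. A log2 fall of 2 or more was listed for 177 features in sickle and 71 in A17, of which 21 and 33 were repressed. The counts of changed features in the 2 lines at 7 dpi, and the median fold changes of those features, therefore also carry how readily a given fold change passed.

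**Figure D2:**
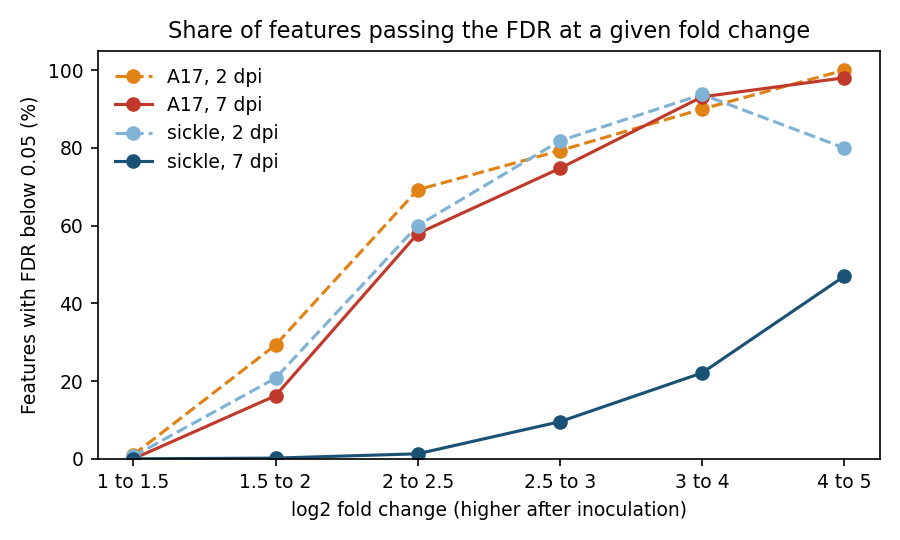
Percentage of features with an FDR below 0.05 (vertical axis) in classes of log2 fold change above 0 (horizontal axis), with 1 line for each line and day in the authors' deposited table. The curve of sickle at 7 dpi is level with A17 at 7 dpi at 0% for a log2 fold change of 1 to 1.5 and lies below the other 3 from there on, at 22.1% for a log2 fold change of 3 to 4 where A17 at 7 dpi reaches 93.1%.

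In sickle, few of the features induced early were induced late. Of the features with a value on both days, 71 were induced at 2 dpi and 90 at 7 dpi, and 5 were induced on both (0.377 by independent lists, one-sided Fisher's exact p = 3.72e-05, adjusted 7.44e-05). No feature was repressed on both days, among 17 and 10 with values on both. The features induced in sickle at 2 dpi had a median log2 fold change of -0.00 in sickle at 7 dpi, with 35 of 71 above 0, and of -0.02 in A17 at 7 dpi, with 34 of 69 above 0. Whether the share kept from 2 to 7 dpi differed between the lines was not tested.

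The central question of the design was whether the response to the fungus depends on the ability to respond to ethylene. At 2 dpi more features were induced in both lines than independent lists would share. Among features with a value in both, 113 were induced in A17 and 69 in sickle, and 37 were induced in both (0.458 by independent lists, one-sided Fisher's exact p = 1.39e-64, adjusted 5.56e-64). Of 26 and 24 repressed, 8 were shared (0.0366 by independent lists, one-sided Fisher's exact p = 6.44e-18, adjusted 1.93e-17). The features induced in sickle had a median log2 fold change of 1.81 in A17, with 67 of 69 above 0, and those induced in A17 had a median of 1.31 in sickle, with 99 of 113 above 0. No feature was induced in 1 line and repressed in the other, but independent lists of these sizes would also be likely to give none. The fold changes of the lines also went together across all features at 2 dpi, which are not independent replicates (rank correlation 0.642, and 0.638 among features that passed in neither line), and the sizes expected of independent lists leave this out.

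At 7 dpi the induced features again went together. Of 356 induced in A17 and 101 in sickle with values in both, 59 were shared (2.06 by independent lists, one-sided Fisher's exact p = 3.21e-74, adjusted 3.85e-73). The rank correlation of the lines was 0.307 over all features at 7 dpi and 0.269 among those that passed in neither line. The sizes expected of independent lists leave this out. The 356 features induced in A17 had a median log2 fold change of 2.41 in sickle, with 334 above 0, and the 101 induced in sickle had a median of 2.45 in A17, with 98 above 0. These medians leave out 73 features induced in A17 without a value in sickle, among them Medtr5g073200.1, and 24 induced in sickle without a value in A17. None of the 34 features repressed in A17 was among the 13 repressed in sickle, a count that says nothing of their overlap, since independent lists of these sizes would share 0.0254 features (one-sided Fisher's exact p = 1). The A17-repressed features had a median of -0.19 in sickle at 7 dpi, with 19 of 34 below 0, and the sickle-repressed features had a median of -0.27 in A17, with 8 of 13 below 0.

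**Figure D3:**
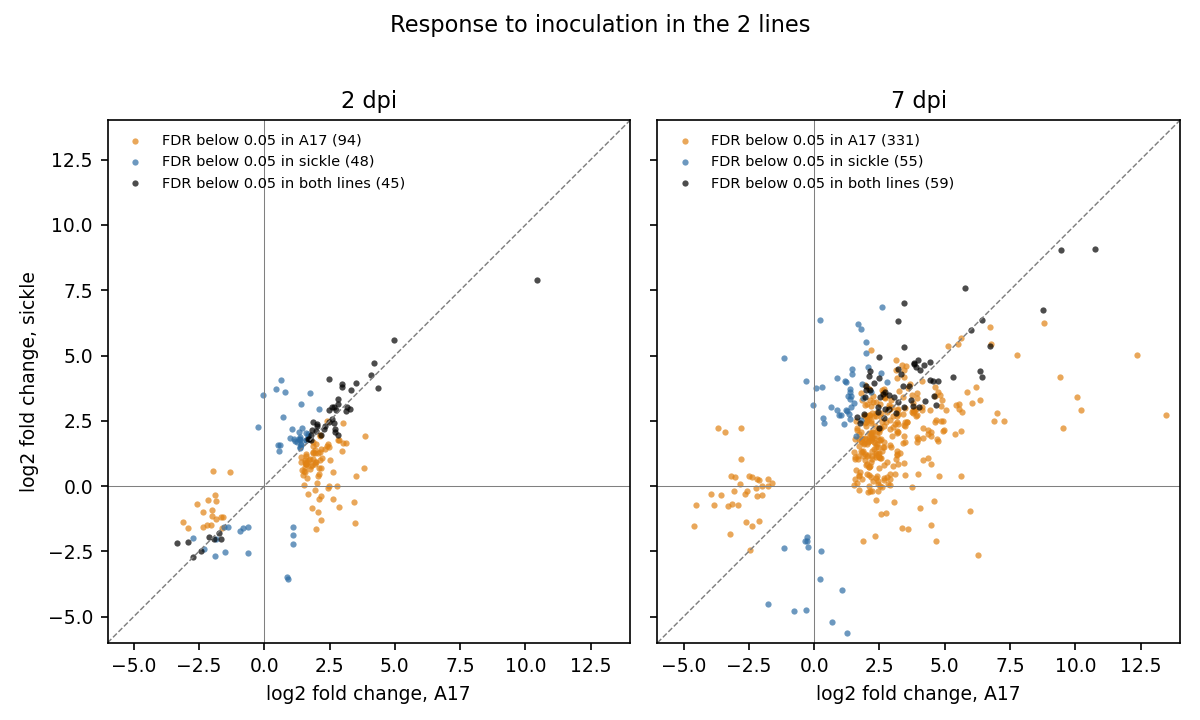
Log2 fold change of inoculated over mock roots in A17 (horizontal axis) and sickle (vertical axis) at 2 dpi and 7 dpi, for features with an FDR below 0.05 in either line in the authors' deposited table. Each point is 1 feature, orange for A17, blue for sickle and black for both lines, and the dashed line marks equal fold changes. At 7 dpi 334 of the 356 features induced in A17 with a value in sickle lie above 0 in sickle, and 73 more without a value in sickle are not drawn.

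Features induced in A17 at 7 dpi had higher fold changes in A17 than in sickle at 2 dpi, when most of them did not pass the FDR in either line. Among 307 such features with both values at 2 dpi, the median was 0.81 in A17 and 0.39 in sickle, and 221 were lower in sickle (median of sickle minus A17 -0.44, two-sided sign-flip permutation test of the mean difference, p = 1e-05, the smallest the permutations can give, adjusted 8e-05 over 8 tests). Features induced in A17 at 2 dpi were also lower in sickle at 7 dpi, with medians of 2.00 in A17 and 1.27 in sickle over 119 features, of which 83 were lower in sickle (median difference -0.71, permutation p = 0.0001, adjusted 0.0004). Features chosen instead for induction in sickle at 7 dpi showed a smaller difference at 2 dpi that did not pass (median of sickle minus A17 -0.11 over 88 features, 50 lower in sickle, permutation p = 0.0836, adjusted 0.134). Nor did the difference at 7 dpi pass for features chosen for induction in sickle at 2 dpi (median of sickle minus A17 -0.20 over 68 features, 38 lower in sickle, permutation p = 0.292, adjusted 0.389). Features are not independent replicates, since all of them come from the same 3 libraries per group, so these p-values are too small by an unknown amount.

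The features induced in A17 at 2 dpi differed in their fold changes at 7 dpi according to whether they passed in sickle at 2 dpi, the day on which the fold changes of the lines went together across all features. The 37 features induced in both lines at 2 dpi had a median log2 fold change at 7 dpi of 0.00 in A17, with 18 of 35 above 0 and 6 induced, and 0.03 in sickle, with 19 of 37 above 0 and 4 induced. The 76 features induced in A17 at 2 dpi whose FDR did not pass in sickle (median of 0.91 in sickle at 2 dpi) had a median of 2.35 in A17 at 7 dpi, with 63 of 75 above 0 and 44 induced. Their median in sickle at 7 dpi was 1.59, with 62 of 73 above 0, although 6 passed the FDR. The medians of the 2 parts differed by 2.35 in A17 (two-sided permutation test over features, p = 0.00046, adjusted 0.00092 over 4 tests) and by 1.56 in sickle (p = 0.00016, adjusted 0.00064). The corresponding split of the features induced in sickle gave differences of 0.01 (permutation p = 0.939) and -0.03 (permutation p = 1). A further 23 features induced in A17 at 2 dpi had no value in sickle on that day, and the 20 of them listed in A17 at 7 dpi had a median of 5.72.

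**Figure D4:**
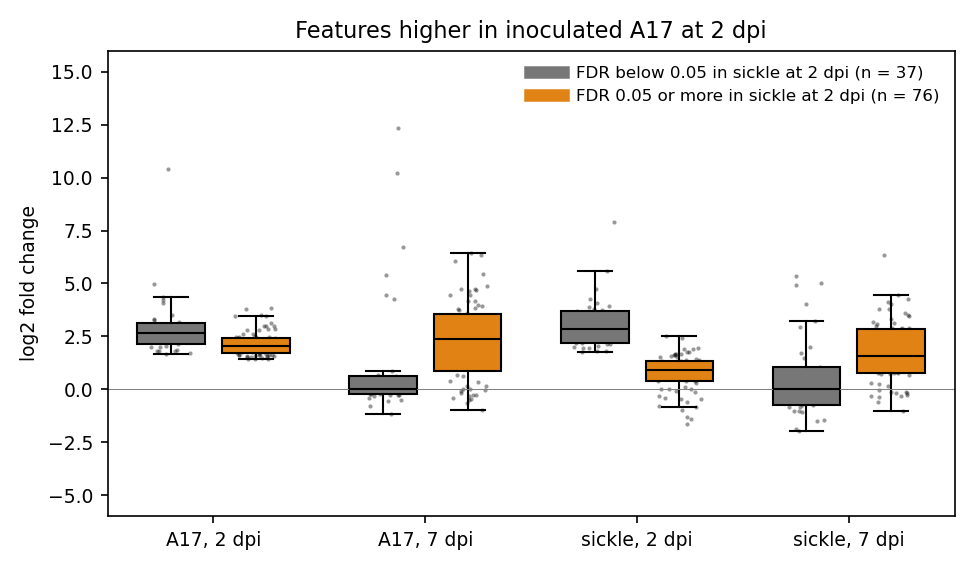
Log2 fold change of features induced in A17 at 2 dpi, in each line and day of the authors' deposited table. Grey boxes hold the 37 features that also passed the FDR in sickle at 2 dpi and orange boxes the 76 that did not, boxes span the quartiles with the median as a line, whiskers reach the farthest value within 1.5 interquartile ranges, and points are features. At 7 dpi the orange medians are 2.35 in A17 and 1.59 in sickle and the grey medians are 0.00 and 0.03.

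Whether the response of any single feature differed between the lines or the days is not reported, since the features that respond in 1 comparison alone could not be tested from the deposited values.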

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

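The tests across features in this part were chosen after the fold changes had been seen, in place of planned fits that need values per library.

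Differences between the lines set these results apart. Features induced in A17 had lower fold changes in sickle than in A17 on the day that had not been used to choose them, by a median of sickle minus A17 of -0.44 for those chosen at 7 dpi and -0.71 for those chosen at 2 dpi. Features induced in sickle gave smaller differences that did not pass, -0.11 for those chosen at 7 dpi and -0.20 for those chosen at 2 dpi. Features are not independent replicates, so p-values over them are too small by an unknown amount. The 9 features repressed in sickle at 7 dpi with values in both lines at 2 dpi had a median of sickle minus A17 of 0.15 at 2 dpi, with 1 of 9 lower in sickle (exact sign-flip test, p = 0.0156, adjusted 0.0416). At an FDR limit of 0.1 the median was 0.19 over 17 features and did not pass (permutation p = 0.262), and at 0.01 it was 0.91 over 3 features, too few for the exact test to pass.

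More features changed in A17 than in sickle at 7 dpi, 466 against 147. Smaller fold changes in sickle as the whole cause are argued against by the features with a log2 fold change of 2 to 3, of which 4.31% passed the FDR in sickle and 63.8% in A17. The approximate standard error was larger in sickle for 268 of the 290 features with an FDR below 0.5 in both lines at 7 dpi, with a median ratio of sickle over A17 of 1.52, against 0.935 at 2 dpi. It is computed from the same fold changes and FDRs, so it restates that a given fold change passed less often and is no separate evidence of a larger spread. The log2 fold changes of all listed features, which do not rest on the FDRs, were also more spread in sickle at 7 dpi. Their robust standard deviation, from the median absolute deviation, was 0.536, against 0.411 in A17 at 7 dpi. At 2 dpi it was 0.403 in A17 and 0.458 in sickle. A wider response over many features would give this as well. A larger spread between the sickle replicates at 7 dpi may explain the pattern, but the table has no values per library and leaves this open.

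Features induced in A17 at 2 dpi that did not pass in sickle were higher at 7 dpi in both lines than those induced in both lines at 2 dpi. False calls in A17 are argued against by their median of 1.59 in sickle at 7 dpi, from libraries that played no part in the choice, with 62 of 73 above 0. A threshold miss in sickle at 2 dpi stays open. The drop to the other line had a median of 1.04 for 76 features passing in A17 alone and 0.70 for 32 passing in sickle alone (difference of medians 0.34), but both sets were chosen on the values in which the drop is measured, so this decides nothing. A later response in sickle may explain the pattern as a hypothesis, but features induced in sickle at 7 dpi gave a median of sickle minus A17 of -0.11 at 2 dpi (permutation p = 0.0836), so a late response, a weak one and a threshold miss in sickle cannot be told apart. The lines also differ in susceptibility per the labels, and the comparisons do not separate this from the response to ethylene.

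Fold changes of the lines went together across all features at 2 dpi, with a rank correlation of 0.642 over features, which are not independent replicates, against 0.307 at 7 dpi. Features that passed the FDR do not account for it, because the rank correlation was 0.638 among features that passed in neither line. A difference between mock and inoculated material shared by both lines on that day, such as harvest order or library provider, may give this. So may a small response shared by many features. Either may also add to the 37 features induced in both lines at 2 dpi, whose medians at 7 dpi were 0.00 and 0.03. The near absence of correlation between the days in A17 (0.0359 among features that passed on neither day) does not settle this, since a shared response could fade or persist between the days, and the 2 explanations cannot be told apart.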

How the results depend on the processing

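The FDR limit of 0.01 and the 2-fold limit were planned for the counts of changed features, and the other alternatives and the tests across features were chosen after seeing the data. Of 78 alternative values, 62 kept their direction and side of 0.05, stayed within 1.5 times the reported count or, for the rank correlations, stayed within the approximate 95% interval of the reported value. The other values moved past these limits (10), lost their call (2) or changed sign (4). At an FDR limit of 0.01, 66 features changed in sickle at 2 dpi and 61 at 7 dpi, 23 were induced in both lines at 7 dpi, 2 were induced on both days in sickle, and 48 adjacent pairs of loci were induced in A17 at 7 dpi. At an FDR limit of 0.1, 228 changed in sickle at 7 dpi and 89 were induced in both lines on that day. A stricter or looser limit changes such counts by construction. Over features with a value in all 4 comparisons, 93 changed in sickle at 7 dpi and 37 adjacent pairs were induced in A17 at 7 dpi, out of fewer features. The rank correlation of the lines at 7 dpi was 0.269 among features that passed in neither line, which leaves out the induced features. Under the FDR limits of 0.01 and 0.1, 1 feature per locus, and values in all 4 comparisons, the differences between lines kept their sign and side of 0.05 for the features induced in A17 at 2 or 7 dpi and in sickle at 7 dpi, as did both differences between parts of the features induced in A17 at 2 dpi. For the features repressed in sickle at 7 dpi the median difference was 0.91 at an FDR limit of 0.01, over 3 features that cannot reach 0.05, and 0.19 at 0.1 (permutation p = 0.262), and neither passed. The split of the features induced in sickle, which passed under no setting, changed sign to -0.13 (FDR limit 0.1) and -0.022 (values in all 4 comparisons) in A17, and to 0.33 (FDR limit 0.01) and 0.0127 (values in all 4 comparisons) in sickle. The cause was not tested. The 2-fold limit removed no feature in any comparison.

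No paired analysis was possible because the table has no values per library, although the labels give the groups the same replicate numbers. For that reason the alternatives of normalization, low-count filters, DESeq2 or limma, fits to subsets of groups, replicate blocks, libraries left out in turn, pseudocounts and gene list tests were planned but not run, and other splits of the samples could not be counted. Depth is unknown, so its effect on the features without a value was not examined.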

Other observations

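All tests in this part were chosen after the fold changes had been seen.

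Induced loci lay next to each other along the chromosomes more often than random placement gave, in each of the 4 comparisons. Among 419 loci induced in A17 at 7 dpi there were 74 adjacent pairs, where random placement gave a mean of 9.79 and at most 26 (one-sided permutation p = 1e-05, the smallest the placements can give, adjusted 2.67e-05 over 8 tests). There were 48 pairs at an FDR limit of 0.01, against a mean of 5.37 and at most 18 at random, and 37 over features with a value in all 4 comparisons, against a mean of 4.88 and at most 17 (one-sided permutation p = 1e-05 for both). Part of the 74 pairs lay in 12 runs of 3 or more loci, and the others were isolated pairs. The longest was a run of 9 on chromosome 1 with log2 fold changes from 2.13 to 10.65 in the authors' deposited table. Only 3 of them were listed in sickle at 7 dpi, between 3.29 and 3.81, and 1 of these passed the FDR there. The other loci of the run, which had the larger fold changes in A17, had no value in sickle at 7 dpi. Chromosome 7 held a run of 5 between 2.65 and 10.77 in the authors' deposited table. In A17 at 2 dpi there were 16 pairs against a mean of 1.02 at random (permutation p = 1e-05, adjusted 2.67e-05). In sickle there were 4 against 0.273 at 2 dpi (permutation p = 0.00019, adjusted 0.000304) and 7 against 0.815 at 7 dpi (permutation p = 3e-05, adjusted 6e-05). Random placement of the induced loci is argued against by these counts. Shared regulation of neighbours and reads shared between near-identical copies may both give such runs, and the pairs cannot separate them without sequences.

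Repressed loci were adjacent more often than at random in 3 of the 4 comparisons. In A17 at 7 dpi there were 6 adjacent pairs among 35 loci against a mean of 0.0658 at random (one-sided permutation p = 1e-05, adjusted 2.67e-05). At 2 dpi there were 2 pairs among 29 loci in A17 (permutation p = 0.00107, adjusted 0.00122) and 2 among 28 in sickle (permutation p = 0.00096, adjusted 0.00122), and in sickle at 7 dpi 0 among 22 (0.0262 at random, permutation p = 1). The pairs in A17 at 7 dpi formed 3 runs of 3. On chromosome 2, a run of 3 lay in the authors' deposited table between -3.68 and -2.81 in A17 at 7 dpi and between -2.41 and -1.80 in A17 at 2 dpi, and in sickle the same 3 loci were between -1.73 and -1.20 at 2 dpi and between 2.07 and 2.23 at 7 dpi, where none passed the FDR. That run was singled out after its values were seen, and its difference between the lines was not tested.

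Changed features lacked a value in another comparison more often than the unchanged listed features did, in 11 of 12 pairs of comparisons by an adjusted p under 0.05 (two-sided Fisher's exact tests). The reason for the missing values is not given in the sources used here, so no conclusion about the response is drawn from this. Of the 466 features that changed in A17 at 7 dpi, 120 (25.8%) had no value in sickle at 2 dpi, against 7.35% of all features listed in A17 at 7 dpi (two-sided Fisher's exact test over features, which are not independent, p = 2.3e-35, adjusted 2.76e-34 over 12 tests). Of the 147 that changed in sickle at 7 dpi, 33 (22.4%) had no value in A17 on that day, against 4.67% of those listed (two-sided Fisher's exact test, p = 3.16e-14, adjusted 7.58e-14). The exception was sickle at 2 dpi, where 7.92% of changed features had no value in A17 on that day against 4.04% of those listed (two-sided Fisher's exact test, p = 0.0671, adjusted 0.0671).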
